A study of Arabidopsis thaliana with 9 samples.

How the data were processed

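RNA from whole 10-day-old Arabidopsis thaliana Col-0 seedlings was hybridised to 9 Affymetrix ATH1 arrays. Per the labels' protocols, seeds were grown in 96-well plates in liquid medium with 1% sucrose at 26 °C, with 16 h of light and 8 h of dark, and with 1% DMSO, alone or with 30 µM hyperphyllin. The labels give 3 groups of 3 biological replicates: wild type with DMSO, wild type with hyperphyllin, and amp1-13 with DMSO. No batch, date or pairing is given in the sources used here.

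The deposited values are log2 signal intensities made with RMA, per the submitters' processing notes. The software, its version and the probe set definition are not given in the sources used here. The log2 scale was read from the values, which range from 2.77 to 14.3, with no missing value. The table holds 22810 probe sets, of which 64 control probe sets were left out and 22746 were tested. The values were used as deposited, with no further normalization and no filter. Array values carry no count depth, so the precision rests on 3 arrays per group.

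Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 9 arrays, empirical Bayes moderation with default settings, and contrasts for hyperphyllin minus wild-type DMSO, amp1-13 minus wild-type DMSO and hyperphyllin minus amp1-13. The fit had 6 residual degrees of freedom and 3.45 prior degrees of freedom. The tests were two-sided, with Benjamini-Hochberg adjustment over 22746 probe sets and a threshold of 0.05 on the adjusted p. A moderated F test over the 3 groups was run the same way. A permutation of 3 against 3 arrays cannot give a p below 0.1.

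Probe sets were named with a table that pairs them with genes: 13513 named 1 gene, 503 named several genes and were not assigned, and 8730 were not named here. Of the named probe sets 13436 matched a reference gene table and 77 did not. For the lists, a gene with several probe sets was represented by the one with the highest mean over the 9 arrays, which gave 13355 genes. For the genes with the largest changes, the probe set with the largest change among those that met the conditions of the naming rule was used. Of the 13513 probe sets naming 1 gene, 283 carry a suffix that marks possible cross-hybridisation.

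Before the data were examined, 29 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Under the rule, the 10 named genes with the largest rise and the 10 with the largest fall were taken for each effect against wild-type DMSO, and 6 in each direction for hyperphyllin against amp1-13. They had to pass the threshold with no overlap between groups. From each list up to 4 members with the largest change under the same conditions were taken, or up to 2 with the smallest p where none passed. The text names some of these 317 gene results, and the check of their stability covers all of them. Only 64 of the 516 genes on the fixed lists were measured by a probe set naming 1 gene, and 3 fixed lists had the minimum of 5 measured members for a set test. A further 31 lists of gene families were therefore built after the gene names were seen and before any fold change was computed. Among them are the lists of nuclear and organelle-encoded genes, autophagy, defence and jasmonate, U-box ligases and cytochromes P450 and those named under other observations.

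Lists were tested with camera in limma, with a preset inter-gene correlation of 0.01, against the 13355 genes. Benjamini-Hochberg adjustment was made separately over the 3 fixed lists and the 31 added lists within each contrast. The background and these families of tests were chosen after the gene names were seen. Alternatives for lists were an estimated correlation, fry, which tests a list against no change and not against the other genes, the replicate number as a block and leaving out genes below the 25th percentile of mean signal. Leaving out wild-type DMSO replicate 2 and 2 rescalings of the arrays were added for lists after the data were seen. Alternatives for probe sets and named genes were filters at the 25th and 50th percentile, quantile normalization again and centring on array medians. Others were a trended and robust prior, array weights, the replicate block, a fit of only the groups compared and leaving out each array in turn. A 2-fold minimum was applied to counts of probe sets only.

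Chance likeness from the shared controls was simulated in 100 draws, each array being a random normal combination of the 9 arrays of residuals. An earlier form of the simulation, which permuted the residual arrays, was replaced because whole groups could fall together and give group means of 0.

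The tests were run on simulated data with 200 changed probe sets among 22746. For the hyperphyllin effect limma recovered 26 of 67 probe sets changed 1.5-fold, 54 of 67 changed 2-fold and 64 of 66 changed 4-fold, with 7 unchanged probe sets called. For the amp1-13 effect it recovered 31 of 67, 52 of 67 and 66 of 66, with 8 unchanged probe sets called. Of 31 simulated lists, camera called the 1 list that was shifted and 0 others. Simulated probe sets were drawn independently of each other, so the runs do not test limma or camera on genes that vary together. The runs held 200 changed probe sets per effect, against 6567 called for hyperphyllin in the data. In the simulation for the shared controls, which kept the correlation between probe sets, unchanged groups gave a median of 0 and a highest value of 2351 higher calls for hyperphyllin.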

Results

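Transcript levels were measured on 9 Affymetrix ATH1 arrays, each hybridised with RNA from whole 10-day-old Arabidopsis thaliana Col-0 seedlings from liquid culture. Wild-type seedlings grown with the solvent DMSO, wild-type seedlings grown with 30 µM of the small molecule hyperphyllin in the same solvent, and amp1-13 mutant seedlings grown with DMSO contributed 3 arrays each. AMP1 encodes a putative glutamate carboxypeptidase. The median log2 signal ranged from 6.45 to 6.52 over the 9 arrays, and the number of arrays limits the precision of every value. The tests set each difference against the spread between these samples, which are described as biological replicates. AMP1 and its paralog LAMP1 were not analysed here, so the genotype label was not checked on the mutated gene. Log2 differences are given with their standard error (SE), from 3 arrays per group and the moderated spread pooled over the 3 groups.

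The comparison of hyperphyllin with DMSO in wild-type seedlings asks which transcripts respond to the compound. The largest rise among named genes was 24.7-fold, in AT3G01830, a calmodulin-like gene (log2 difference 4.63 ± 0.62, adjusted p = 0.000892). Its log2 signals with DMSO had an SD of 1.31 (n = 3), so the size and rank of this fold are uncertain. AT1G66090, a TIR-NBS resistance-type gene, rose 19.9-fold (adjusted p = 0.000134), and the AP2/ERF-type gene AT1G22810 rose 17.5-fold (adjusted p = 0.000383). ATPMEPCRB (AT4G02330), a pectin methylesterase gene, rose 17-fold (adjusted p = 7.95e-05), while its family member ATPMEPCRD (AT2G43050) fell to a level 8.77-fold lower (adjusted p = 3.88e-05). GRX480 (AT1G28480), a glutaredoxin gene, had log2 signals of 5.99 ± 0.76 (SD, n = 3) with DMSO and 10.04 ± 0.51 (SD, n = 3) with hyperphyllin, a rise of 16.5-fold. The other large rises were AT2G34930 (17-fold), AT5G12340 (15.7-fold), GAT1_2.1 (AT1G15040), a glutamine amidotransferase gene (13.1-fold), AT4G22470 (11.1-fold) and the calmodulin-like gene CML37 (AT5G42380) (10.7-fold). The largest fall was in AT4G01390, which was 19.9-fold lower (log2 difference -4.32 ± 0.20, adjusted p = 2.82e-05). AT4G33720, a CAP family gene related to PR-1, was 15.2-fold lower, AT1G73120 was 14.6-fold lower and AT1G64360 was 10.2-fold lower. AT1G22160, AT5G39520, AT1G80130, AT5G02580 and AT1G06980 were lower by between 6.36-fold and 8.64-fold. The 25th percentile of mean signal was 4.39, and the files give no detection call. AT1G22810 and CML37 with DMSO (mean log2 3.79 and 4.31) and AT1G64360 with hyperphyllin (4.09) lay below it, so the sizes of their folds are uncertain.

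Of 38 nuclear genes for photosynthesis and chlorophyll, 27 were higher with hyperphyllin, 2 were lower and the rest did not pass the test (camera adjusted p = 7.88e-15, and adjusted p = 0.466 with an estimated correlation). Among them were the tetrapyrrole synthesis genes HEMA2 (AT1G09940), which rose 4.58-fold (adjusted p = 0.000339), HEME1 (AT3G14930), which rose 2.28-fold, and HEMB1 (AT1G69740), which rose 2.13-fold. The photosystem II repair gene PSB27 (AT1G03600) rose 2.44-fold (adjusted p = 0.000271). Of 22 plastid-encoded genes for transcription, translation and related functions, 13 were higher and 1 was lower (camera adjusted p = 2.86e-07, and adjusted p = 0.466 with an estimated correlation). The ribosomal protein genes rpl16 and rpl14 rose 3.13-fold (adjusted p = 0.00161) and 2.68-fold (adjusted p = 0.00139), and the RNA polymerase gene rpoC1 rose 2.51-fold (adjusted p = 0.00108). Of 47 plastid-encoded photosynthesis genes, 12 were higher and 3 were lower (camera adjusted p = 0.00887, and adjusted p = 0.891 with an estimated correlation, and 0.301 with fry). Over all probe sets 28.9% passed the threshold with hyperphyllin, so the count of members called in this list is near that share. The test fry sets a list against no change, and camera sets it against the other genes. The photosystem I assembly gene ycf3 rose 3.05-fold, and the photosystem II genes psbC and psbD rose 2.43-fold and 2.18-fold.

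Of 10 autophagy genes, 7 were lower with hyperphyllin and 0 were higher (camera adjusted p = 0.000126, and adjusted p = 0.466 with an estimated correlation). ATG8G (AT3G60640), ATG8D (AT2G05630) and ATG8B (AT4G04620), which encode ubiquitin-like proteins of the autophagosome membrane, were 2.18-fold, 2.07-fold and 1.98-fold lower. Of 28 defence and jasmonate genes, 12 were higher and 3 were lower (camera adjusted p = 0.00147, and adjusted p = 0.466 with an estimated correlation). The transcription factor genes WRKY53 (AT4G23810) and WRKY22 (AT4G01250) rose 7.34-fold (adjusted p = 0.00704) and 6.42-fold (adjusted p = 0.000361). Of 9 genes for U-box ubiquitin ligases, 5 were higher and 0 were lower (camera adjusted p = 0.025, and adjusted p = 0.466 with an estimated correlation). PUB23 (AT2G35930), PUB24 (AT3G11840) and PUB22 (AT3G52450), which act in immune signalling, rose 6.69-fold, 3.5-fold and 3.21-fold. Wild-type DMSO replicate 2 lay apart from the other control arrays, and without it the U-box list had a camera adjusted p of 0.0887 and the defence list of 0.0303.

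Few of the genes listed in advance from hormone and stress biology were measured by a probe set naming 1 gene (64 of 516). Both measured cytokinin response regulators missed the threshold: RR16 (AT2G40670) had a log2 difference of -0.72 ± 0.36 (adjusted p = 0.174) and ARR15 (AT1G74890) of -0.03 ± 0.09 (adjusted p = 0.854), and RR16 passed it at an adjusted p of 0.0169 with array weights and 0.0381 without wild-type DMSO replicate 2. Of the cytokinin glucosyltransferase genes, UGT76C2 (AT5G05860) rose 1.64-fold (adjusted p = 0.00837) and UGT76C1 (AT5G05870) fell to a level 1.42-fold lower (adjusted p = 0.0066). The meristem regulators CLV3 (AT2G27250) and PHV (AT1G30490) had log2 differences of -0.01 ± 0.23 (adjusted p = 0.975) and 0.11 ± 0.14 (adjusted p = 0.613). The mean signals of ARR15 and CLV3 lay below the 25th percentile, so their small differences do not show that these genes were unchanged. None of 7 auxin response genes and none of 6 anthocyanin and flavonoid genes passed the threshold, and adjusted over the list alone the counts were also 0 and 0 (limma camera adjusted p = 0.901 and 0.895). In limma 1 and 2 of these genes had an unadjusted p under 0.05. The adjusted p of the auxin response gene AT2G18010 was 0.0216 with array weights, 0.0406 without wild-type DMSO replicate 2, 0.0388 without amp1-13 DMSO replicate 3 and 0.0423 with only the 2 groups, and that of GH3.3 (AT2G23170) was 0.0373 with array weights. That of the flavonol gene UGT78D1 (AT1G30530) was 0.0495 with the 25th percentile filter, 0.0451 with the 50th percentile filter, 0.0408 after quantile normalization, 0.0308 after centring, 0.0151 with array weights and 0.0241 without wild-type hyperphyllin replicate 3. Of 7 xenobiotic detoxification genes 2 were higher, and 3 when adjusted over the list alone (camera adjusted p = 0.67). The 2 were the glutathione transferase gene GSTU22 (AT1G78340), which rose 2.05-fold (adjusted p = 0.00964), and UGT73B5 (AT2G15480), which rose 1.64-fold (adjusted p = 0.015, and 0.0503 without wild-type hyperphyllin replicate 2). The ADP-glucose pyrophosphorylase gene APL3 (AT4G39210), of starch synthesis, was 3.39-fold lower (adjusted p = 0.00075). FMA (AT3G24140), which encodes the guard cell regulator FAMA, was 1.75-fold lower (adjusted p = 0.0089), and the cold-responsive gene COR15B (AT2G42530) was 2.26-fold lower (adjusted p = 0.0123). Another cold-responsive gene, COR47 (AT1G20440), rose 1.65-fold (adjusted p = 0.0299), and its adjusted p was 0.0775 without wild-type DMSO replicate 1, 0.102 without wild-type DMSO replicate 3, 0.086 without wild-type hyperphyllin replicate 1, 0.0862 without wild-type hyperphyllin replicate 2 and 0.0596 with only the 2 groups.

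Over 22746 probe sets, limma called 3023 higher and 3544 lower with hyperphyllin. Together these are 28.9% of the probe sets, a share to set beside the counts of list members. The count of higher probe sets was 1921 without wild-type DMSO replicate 3, and the count of lower ones was 2356 without wild-type DMSO replicate 1, 1960 without wild-type DMSO replicate 3, 2273 without wild-type hyperphyllin replicate 1 and 2103 without wild-type hyperphyllin replicate 2. In 8993 probe sets, or 39.5%, the 3 values of one group did not overlap the 3 of the other, where chance gives 10%.

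The comparison of amp1-13 with wild type, both with DMSO, asks which transcripts the mutation changes. The largest rise among named genes was 7.57-fold, in DFR (AT5G42800), dihydroflavonol reductase of anthocyanin synthesis, from a log2 signal of 5.53 ± 0.68 (SD, n = 3) to 8.45 ± 0.29 (SD, n = 3; adjusted p = 0.00054). GAT1_2.1 rose 7.45-fold (adjusted p = 0.00133), AT4G22470 rose 7.25-fold, AT3G15450 rose 7.02-fold and AT2G32190 rose 5.92-fold. AT1G66090, AT2G20670 and AT3G59080 rose by between 5.12-fold and 5.56-fold. AT3G01830 rose 6.54-fold with adjusted p = 0.0143, and AT4G29780 rose 5.43-fold with adjusted p = 0.017. The size of the fold of AT3G01830 is uncertain, since its wild-type DMSO signals had an SD of 1.31 (n = 3). For AT3G01830 the adjusted p was 0.053 without wild-type DMSO replicate 3, and for AT4G29780 it was 0.0746 without wild-type DMSO replicate 3 and 0.0607 without amp1-13 DMSO replicate 1. The largest fitted fall was 12-fold, in QQS (AT3G30720), a regulator of starch content, with a log2 difference of -3.58 ± 0.27 (adjusted p = 0.000212). AT5G57760 was 6.32-fold lower, AT1G29090 was 5.82-fold lower and the pectin methylesterase gene ATPMEPCRD was 5.44-fold lower. AT1G06980, AT1G64590, AT5G62280, AT1G29270, AT3G53250 and AT1G22160 were lower by between 4.61-fold and 5.6-fold. In amp1-13 QQS and AT3G53250 (mean log2 3.89 and 3.91) lay below the 25th percentile of mean signal, so the sizes of their folds are uncertain.

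Of the 38 nuclear photosynthesis and chlorophyll genes, 27 were higher in amp1-13 and 0 were lower (camera adjusted p = 7.93e-20, and adjusted p = 0.29 with an estimated correlation). The Calvin cycle genes PRK (AT1G32060) and SBPASE (AT3G55800) rose 2.9-fold (adjusted p = 0.000321) and 2.29-fold (adjusted p = 0.000361), and PSBY (AT1G67740), of photosystem II, rose 2.47-fold. All 4 measured members of the photosynthesis list written in advance were higher, as were all 4 when adjusted over the list alone, among them Rubisco activase (RCA (AT2G39730), 1.87-fold, adjusted p = 0.00159) and LHCB4.1 (AT5G01530) (1.52-fold, adjusted p = 0.00493). Another, LHCB4.2 (adjusted p = 0.0174), lost its call without wild-type DMSO replicate 3, amp1-13 DMSO replicate 1 or amp1-13 DMSO replicate 2 (highest adjusted p 0.058). With hyperphyllin 3 of the 4 were higher, RCA by 1.78-fold (adjusted p = 0.00139). PORB (adjusted p = 0.0227) lost its hyperphyllin call without wild-type DMSO replicate 1, wild-type DMSO replicate 3 or wild-type hyperphyllin replicate 2 (highest adjusted p 0.0818). Plastid-encoded photosynthesis genes were higher in amp1-13 in 22 of 47 cases (camera adjusted p = 1.01e-12, and adjusted p = 0.293 with an estimated correlation). Among these psbC rose 3.93-fold (adjusted p = 0.000309) and psbD rose 3.53-fold (adjusted p = 0.00108). Plastid gene expression genes were higher in 13 of 22 cases (camera adjusted p = 2.66e-09, and adjusted p = 0.293 with an estimated correlation), with rpl16 at 3.41-fold (adjusted p = 0.00198). Of 15 mitochondria-encoded genes 2 were higher (camera adjusted p = 0.00939, and adjusted p = 0.29 with an estimated correlation, and 0.136 without genes below the 25th percentile of mean signal). These were nad2, which rose 1.69-fold, and ccb382, which rose 1.53-fold. The signal of nad2 lay below the 25th percentile in both groups, so the size of its fold is uncertain. Without wild-type DMSO replicate 2 the mitochondrial list had a camera adjusted p of 0.0686.

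The anthocyanin and flavonoid list, fixed in advance, was higher in amp1-13: 3 of 6 members rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00343, and adjusted p = 0.12 with an estimated correlation). Besides DFR these were the anthocyanin glycosyltransferase genes UF3GT (AT5G54060), which rose 1.77-fold (adjusted p = 0.00178), and AT4G14090, which rose 1.67-fold (adjusted p = 0.0013). The flavonol rhamnosyltransferase gene UGT78D1 (AT1G30530) was 1.69-fold lower (adjusted p = 0.00968). Autophagy genes were lower in 6 of 10 cases and higher in 0 (camera adjusted p = 0.0116, and adjusted p = 0.515 with an estimated correlation), with ATG8G 2.02-fold lower (adjusted p = 0.00559). Of the 28 defence and jasmonate genes 9 were higher and 2 were lower (camera adjusted p = 0.0266, and adjusted p = 0.293 with an estimated correlation), with WRKY22 at 3.55-fold (adjusted p = 0.003) and WRKY6 (AT1G62300) at 3.21-fold (adjusted p = 0.000744). U-box ligase genes were higher in 3 of 9 cases (camera adjusted p = 0.0116, and adjusted p = 0.293 with an estimated correlation, and 0.0535 with fry). PUB23 rose 3.35-fold with adjusted p = 0.0165, and its adjusted p was 0.0726 without wild-type DMSO replicate 3 and 0.0516 without amp1-13 DMSO replicate 1. Without wild-type DMSO replicate 2 the defence list had a camera adjusted p of 0.176 and the U-box list of 0.0665.

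Cytokinin and meristem genes measured in amp1-13 gave the following values. RR16 had a log2 difference of -0.72 ± 0.36 (adjusted p = 0.188), CLV3 of 0.60 ± 0.23 (adjusted p = 0.094) and PHV of 0.33 ± 0.14 (adjusted p = 0.107). None of these passed the threshold. Adjusted over the list alone CLV3 and PHV were both higher, but that list had 2 measured members and the other lists were not adjusted for. In amp1-13, 8161 of 22746 probe sets had an unadjusted p under 0.05 in limma, so this is weak evidence of a rise. The adjusted p of RR16 was 0.0445 with array weights and 0.0416 without wild-type DMSO replicate 2, that of CLV3 0.0256 with array weights and that of PHV 0.0124 with array weights and 0.0157 without wild-type DMSO replicate 2. The mean signal of CLV3 lay below the 25th percentile, so the size of its difference is uncertain. UGT76C1 was 1.39-fold lower (adjusted p = 0.0113), and UGT76C2 rose 1.47-fold (adjusted p = 0.0301). The adjusted p of UGT76C2 was 0.0941 without wild-type DMSO replicate 3, 0.106 without amp1-13 DMSO replicate 2, 0.076 without amp1-13 DMSO replicate 3 and 0.0565 with only the 2 groups. Of 7 auxin response genes 1 was lower, also when adjusted over the list alone (camera adjusted p = 0.957): IAA29 (AT4G32280), which was 3.2-fold lower (adjusted p = 0.0287). Its adjusted p was 0.0806 without wild-type DMSO replicate 1, 0.0929 without wild-type DMSO replicate 3, 0.0779 without amp1-13 DMSO replicate 1, 0.0972 without amp1-13 DMSO replicate 2 and 0.0518 without amp1-13 DMSO replicate 3. Of 7 xenobiotic detoxification genes 1 was higher and 1 was lower, also when adjusted over the list alone (camera adjusted p = 0.56). UGT73C1 (AT2G36750) rose 1.42-fold (adjusted p = 0.0161, and 0.0616 without amp1-13 DMSO replicate 2), and GSTU20 (AT1G78370) was 1.71-fold lower (adjusted p = 0.03). The adjusted p of GSTU20 was 0.103 without wild-type DMSO replicate 1, 0.117 without wild-type DMSO replicate 3, 0.0889 without amp1-13 DMSO replicate 1, 0.097 without amp1-13 DMSO replicate 2 and 0.0501 without amp1-13 DMSO replicate 3. UGT73C1 lay below the 25th percentile of mean signal in both groups (mean log2 3.88 and 4.38), so the size of its fold is uncertain. FMA was 1.85-fold lower (adjusted p = 0.00831) and COR15B was 3.51-fold lower (adjusted p = 0.00267).

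Over 22746 probe sets, limma called 2289 higher and 2835 lower in amp1-13. Together these are 22.5% of the probe sets, a share to set beside the counts of list members. The count of higher probe sets was 3864 without wild-type DMSO replicate 2, 1295 without wild-type DMSO replicate 3 and 1492 without amp1-13 DMSO replicate 2, and the count of lower ones was 1592 without wild-type DMSO replicate 1, 1250 without wild-type DMSO replicate 3, 1424 without amp1-13 DMSO replicate 1 and 1437 without amp1-13 DMSO replicate 2. In 8032 probe sets, or 35.3%, the values of the groups did not overlap, where chance gives 10%.

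Hyperphyllin and amp1-13 seedlings were compared directly to find transcripts that separate the compound from the mutation. AT4G33720 separated them most, at 34.4-fold lower with hyperphyllin (log2 difference -5.10 ± 0.24, adjusted p = 3.41e-05). Its log2 signal was 10.65 ± 0.43 in wild type with DMSO, 6.72 ± 0.40 with hyperphyllin and 11.83 ± 0.13 in amp1-13 (SD, n = 3 each). AT5G39520 was 21.2-fold lower with hyperphyllin than in amp1-13, AT4G01390 was 5.88-fold lower, the beta-glucosidase gene BGLU28 (AT2G44460) was 5.68-fold lower, AT1G57590 was 5.44-fold lower and AT3G05400 was 5.11-fold lower. AT1G22810 was 11.9-fold higher with hyperphyllin (adjusted p = 0.00265), the defensin gene PDF1.4 (AT1G19610) was 8.99-fold higher (adjusted p = 0.00356) and AT2G34930 was 8.34-fold higher. QQS was 6.23-fold higher and the thionin gene THI2.2 (AT5G36910) was 5.86-fold higher (adjusted p = 5.02e-05). AT1G76640 was 7.78-fold higher with adjusted p = 0.0271, and its adjusted p was 0.0776 without wild-type hyperphyllin replicate 1, 0.112 without wild-type hyperphyllin replicate 2, 0.133 without amp1-13 DMSO replicate 2 and 0.102 without amp1-13 DMSO replicate 3. In amp1-13 AT1G22810, PDF1.4 and QQS (mean log2 4.34, 4.35 and 3.89) lay below the 25th percentile of mean signal, so the sizes of their folds are uncertain.

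The anthocyanin and flavonoid list was lower with hyperphyllin than in amp1-13, with 3 of 6 members past the threshold and 5 when adjusted over the list alone (camera adjusted p = 9.02e-06, and adjusted p = 0.0284 with an estimated correlation). DFR was 4.48-fold lower (adjusted p = 0.00377), UF3GT was 2.1-fold lower (adjusted p = 0.00125) and AT4G14090 was 1.64-fold lower (adjusted p = 0.00333). In this comparison these 3 genes were chosen after their values were seen. Against wild-type DMSO, hyperphyllin gave DFR a log2 difference of 0.76 ± 0.30 (adjusted p = 0.0929), and its adjusted p was 0.0206 with array weights and 0.00676 without wild-type DMSO replicate 1. Plastid-encoded photosynthesis genes were lower with hyperphyllin than in amp1-13 in 6 of 47 cases (camera adjusted p = 2.6e-09, and adjusted p = 0.771 with an estimated correlation, and 0.203 with fry). Of 24 cytochrome P450 genes 5 were lower (camera adjusted p = 0.000825, and adjusted p = 0.149 with an estimated correlation). limma called 677 probe sets higher and 762 lower with hyperphyllin than in amp1-13, together 6.33% of the probe sets tested. The count of higher probe sets was 1094 without wild-type DMSO replicate 2, 382 without wild-type hyperphyllin replicate 1, 251 without wild-type hyperphyllin replicate 2, 197 without amp1-13 DMSO replicate 2 and 304 without amp1-13 DMSO replicate 3, and the count of lower ones was 361 without wild-type hyperphyllin replicate 2, 309 without amp1-13 DMSO replicate 2 and 416 without amp1-13 DMSO replicate 3.

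**Figure D1:**
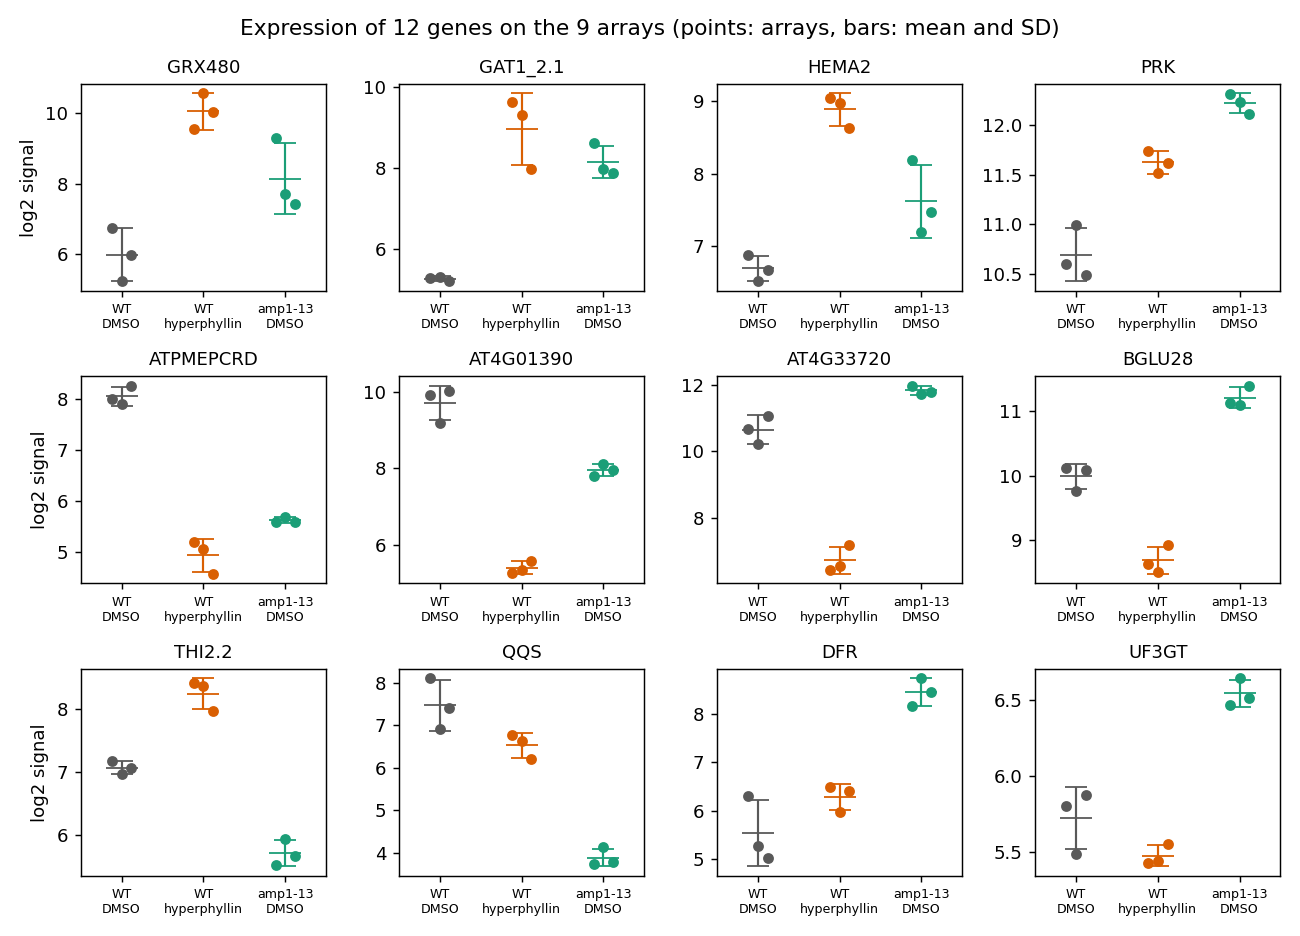
Log2 signal of 12 named genes on the 9 arrays, as points for single arrays with the group mean and SD of 3 arrays as bars. GRX480, GAT1_2.1, HEMA2 and PRK lay higher, and ATPMEPCRD and AT4G01390 lower, in both groups than in wild type with DMSO, while AT4G33720, BGLU28 and THI2.2 moved in opposite directions. The adjusted p of GRX480 in amp1-13 was 0.0171, and 0.0608 without wild-type DMSO replicate 3.

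The effects of hyperphyllin and of amp1-13 were compared across genes. Among the probe sets past the threshold in both comparisons, 1533 were higher in both, 2041 were lower in both and 67 moved in opposite directions. Genes that fell with hyperphyllin and rose in amp1-13 were AT4G33720 (log2 differences -3.92 ± 0.24 and 1.18 ± 0.24), AT5G39520 (-2.95 ± 0.30 and 1.46 ± 0.30) and BGLU28 (-1.29 ± 0.14 and 1.22 ± 0.14). THI2.2 rose with hyperphyllin and fell in amp1-13 (1.19 ± 0.15 and -1.36 ± 0.15). Of the 3574 probe sets that moved in the same direction, 241 also differed between hyperphyllin and amp1-13 in the direct test. The Pearson correlation of the log2 differences across 22746 probe sets, which are not independent replicates, was 0.776 and the Spearman correlation 0.771. Both comparisons use the same 3 control arrays, so likeness arises without any effect. In 100 simulated sets of unchanged groups against shared controls the correlation averaged 0.559, ranging from -0.586 to 0.964, and the covariance averaged 0.0157 with a highest value of 0.113, against 0.201 observed. The simulations gave on average 21.6 shared higher and 19.1 shared lower calls, with highest values of 2162 and 1912. All of these came from 1 set, and the other 99 shared no call. The observed correlation and shared higher count lie within the simulated range, and the covariance and shared lower count above it. A correlation at least as high as the observed one arose in 29 of the 100 sets, so the correlation alone is no evidence of likeness. Independent lists of the observed sizes would share 304 higher and 442 lower probe sets by chance. The shared higher count was 2999 without wild-type DMSO replicate 2 and 843 without wild-type DMSO replicate 3, and the shared lower count was 1044 without wild-type DMSO replicate 1, 3299 without wild-type DMSO replicate 2, 811 without wild-type DMSO replicate 3, 1250 without wild-type hyperphyllin replicate 2, 1078 without amp1-13 DMSO replicate 1 and 1111 without amp1-13 DMSO replicate 2.

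**Figure D2:**
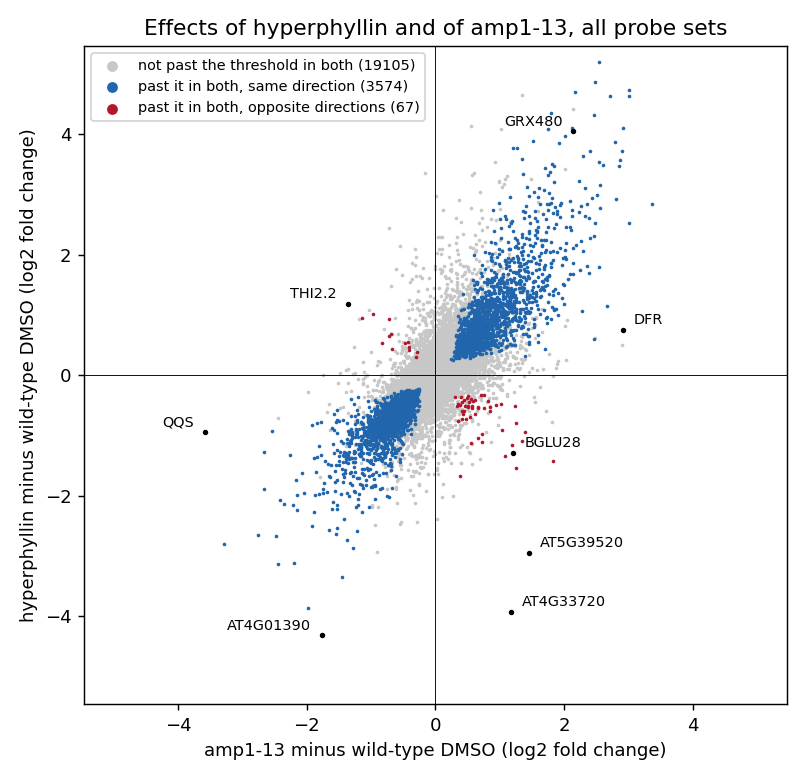
Log2 fold change with hyperphyllin (vertical axis) against that of amp1-13 (horizontal axis), both relative to wild type with DMSO, for 22746 probe sets. Blue points passed the threshold in both comparisons in the same direction (3574), red points in opposite directions (67), grey points did not pass in both, and black points mark named genes.

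**Figure D3:**
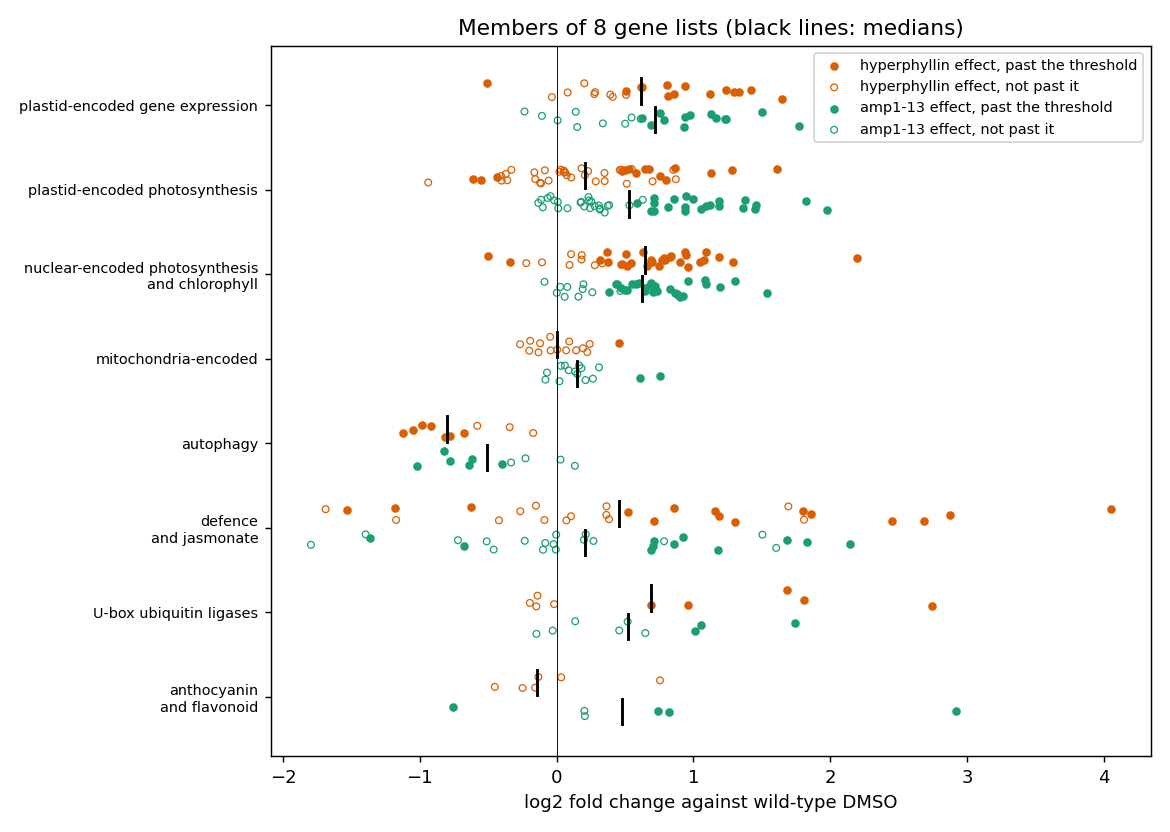
Log2 fold change of the members of 8 gene lists against wild type with DMSO, with hyperphyllin (orange) and in amp1-13 (green). Filled points passed the threshold, open points did not, and black lines are medians, which for autophagy were -0.80 with hyperphyllin and -0.51 in amp1-13.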

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

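The alternatives for lists that leave out wild-type DMSO replicate 2 or rescale the arrays were chosen after the data were seen, and the others before. Leaving out 1 array at a time gave 1921 to 4422 higher and 1960 to 4447 lower probe sets for hyperphyllin, and 1295 to 3864 higher and 1250 to 4078 lower for amp1-13. It gave 197 to 1094 higher and 309 to 1133 lower for hyperphyllin against amp1-13. Any difference among the groups was called in 4048 to 9661 probe sets, against 6872, the lowest without wild-type DMSO replicate 3. Shared calls were 843 to 2999 higher and 811 to 3299 lower, and the correlation of the effects was 0.717 to 0.813. Fewer arrays lower the power, but leaving out wild-type DMSO replicate 2 raised the counts of probe sets. Without wild-type DMSO replicate 3, 58.4% of the probe sets called for hyperphyllin and 48.9% of those called for amp1-13 were called again.

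With array weights, the counts were 4988 higher and 5497 lower for hyperphyllin, 4412 and 4951 for amp1-13, 1735 and 1688 for hyperphyllin against amp1-13, 11624 for any difference, and 3311 and 4016 for shared calls. The cause was not tested. A 2-fold minimum, which can only remove calls, left 1005 higher and 558 lower, 665 and 318, and 266 and 259. The filters, rescalings, prior and fits of only 2 groups kept every count of calls within 1.5 times. With an estimated correlation camera called 0 of 6 lists for hyperphyllin, 0 of 13 for amp1-13 and 1 of 6 for hyperphyllin against amp1-13. The lists with an unadjusted p under 0.05 there numbered 2, 4 and 4. The calls lost with the estimate depend on the low preset inter-gene correlation, which treats the genes of a list as nearly independent. The small camera p-values of these lists rest on the same setting. Of the called lists, 5 of 6, 11 of 13 and 4 of 6 also passed fry, whose null is no change in the list and not likeness to other genes. Leaving out dim genes kept 6 of 6, 9 of 13 and 5 of 6, and leaving out wild-type DMSO replicate 2 kept 5 of 6, 9 of 13 and 6 of 6. No called list changed direction under any list alternative.

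Of the 317 gene results named by the rule, 274 passed the threshold and 213 were the same under every alternative in which they were tested. Without 1 array 73 lost their call in at least 1 fit, 31 lost it under another alternative, 27 gained one and 7 changed sign. Among the 52 with the largest changes, 49 were the same and 3 lost their call without 1 array. The rule chose these 52 because they passed the threshold on the same arrays, so their stability does not describe other probe sets. The sign changes were in results that did not pass the threshold. With hyperphyllin ARR15 had a log2 difference of -0.0272, and 0.0106 after quantile normalization and between -0.0698 and 0.0254 without 1 array. CLV3 had a log2 difference of -0.0134, and 0.0258 after quantile normalization, 0.00889 with array weights and between -0.0374 and 0.029 without 1 array. GI had a log2 difference of 0.16, and between -0.0319 and 0.50 without 1 array. GI passed the threshold at a log2 difference of 0.50 (adjusted p = 0.0215) with array weights and a log2 difference of 0.50 (adjusted p = 0.0105) without wild-type DMSO replicate 2. PDF1.2 had a log2 difference of -1.69, and between -2.68 and 0.0559 without 1 array. PDF1.2 passed the threshold at a log2 difference of -3.83 (adjusted p = 0.00887) with array weights. GUT2 had a log2 difference of 0.13, and between -0.0224 and 0.34 without 1 array. GUT2 passed the threshold at a log2 difference of 0.34 (adjusted p = 0.0416) without wild-type DMSO replicate 2. In amp1-13 ARR15 had a log2 difference of 0.0364, and between -0.0161 and 0.0707 without 1 array. UGT74B1 had a log2 difference of 0.0482, and between -0.0562 and 0.18 without 1 array.

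No pairing by replicate number was detected: deviations of same-numbered arrays correlated between -0.197 and 0.226, and 3 of 9 pairs were over 0.1. Deviations of arrays with different numbers in different groups correlated between -0.251 and 0.357. With the replicate block the counts were 2892 and 3383 for hyperphyllin, 2183 and 2686 for amp1-13, 643 and 695 for hyperphyllin against amp1-13, and 6450 for any difference. Of 322 gene results, 9 lost and 1 gained a call with it. Leaving out probe sets below the 25th percentile of mean signal, at 4.39, removed 15 of the 322 gene results, which were not tested there, and of the other 307 it changed 2 calls, both gained. The 50th percentile filter left 228 of the 322 to test.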

Other observations

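Tests on wild-type DMSO replicate 2, on the shared controls and on other splits of the arrays were written before their results were seen, and the comparison of plastid with mitochondrial transcripts after. The values of lists without wild-type DMSO replicate 2 and after quantile normalization were chosen after the data were seen. Camera called further gene families in amp1-13, and each of these calls was lost with an estimated correlation. Of 22 beta-glucosidase genes 4 were higher and 0 were lower (camera adjusted p = 0.0354, and adjusted p = 0.293 with an estimated correlation), and the camera adjusted p was 0.0724 without wild-type DMSO replicate 2. Of 11 genes for nitrate and peptide transporters 4 were higher (camera adjusted p = 0.0354, and adjusted p = 0.293 with an estimated correlation, and 0.0558 without genes below the 25th percentile of mean signal), among them the glucosinolate transporter gene GTR1 (AT3G47960), which rose 2.32-fold (adjusted p = 0.00144). Of 18 genes for RNA polymerase subunits and ribosome assembly 6 were lower and 0 were higher (camera adjusted p = 0.0303, and adjusted p = 0.293 with an estimated correlation, and 0.0558 without genes below the 25th percentile of mean signal). Of 14 endoplasmic reticulum protein folding genes 3 were higher and 1 was lower (camera adjusted p = 0.0303, and adjusted p = 0.406 with an estimated correlation, and 0.0976 with fry, and 0.0703 without genes below the 25th percentile of mean signal), and the camera adjusted p was 0.0829 after quantile normalization. A list of 9 flavonoid modification genes, which shares DFR, UF3GT, AT4G14090 and UGT78D1 with the anthocyanin list, had 4 higher and 1 lower (camera adjusted p = 0.00956, and adjusted p = 0.293 with an estimated correlation). In hyperphyllin against amp1-13 4 of them were lower (camera adjusted p = 0.000176, and adjusted p = 0.149 with an estimated correlation). The autophagy list was lower in hyperphyllin than in amp1-13 with 0 of 10 members past the threshold, and 4 at an unadjusted p under 0.05 in limma (camera adjusted p = 0.00615, and adjusted p = 0.771 with an estimated correlation, and 0.305 with fry), and the mitochondria-encoded list with 1 of 15 (camera adjusted p = 0.00975, and adjusted p = 0.212 with an estimated correlation, and 0.118 without genes below the 25th percentile of mean signal).

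Other splits of the arrays were counted. For hyperphyllin 1 of 10 splits gave as many probe sets as the real 6567, the highest other being 0, for amp1-13 1 of 10 gave as many as 5124, the highest other being 0, and for hyperphyllin against amp1-13 1 of 10 gave as many as 1439, the highest other being 2. These 10 splits are too few for a share under 0.05. For any difference among the groups, 1 of 100 drawn splits, the real one, gave as many as 6872, the highest other being 3218. This argues against a chance assignment of the arrays to groups. For shared calls in the same direction 1 of 100 gave as many as 3574, the highest other being 2649. The splits show here that the groups differ, but do not test whether the 2 effects share calls beyond their shared controls. Of 100 simulated sets of unchanged groups against shared controls, 1 gave as many shared calls (4074).

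Wild-type DMSO replicate 2 lay apart from replicates 1 and 3, with an array weight of 0.227 against 0.662 and 2.51. A distortion that depends on brightness is argued against, since a smooth curve on mean signal took up 0.371% of the variance of its deviation. Over 2870 probe sets whose groups lay within 0.1 log2, its deviation had an SD 1.18 times the median of the other 8 arrays, against 1.57 times over all probe sets. This ratio, under the bound of 1.5 set for the test, leaves open seedlings or RNA of a treated or mutant group in this sample. The difference of wild-type DMSO replicate 2 from replicates 1 and 3 correlated with the mean effect at 0.325 and 0.566. On principal component 3, an axis with 8.86% of the variance between arrays, it lay at -35.8 and the other arrays between -6.38 and 19.8. This part of its deviation was not shared by the treated or mutant arrays, so the ratio and correlations do not show such material. The SD of 0.152 over the unchanged probe sets was above the highest of the other 8 arrays, 0.148, so added noise in this array stays open, as does a control sample that differed in growth stage or handling, untested.

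The effects of hyperphyllin and amp1-13 were alike in their covariance, which lay above all 100 simulated sets of unchanged groups. Their correlation was reached in 29 of those sets. With the controls divided so that no array served both effects, the lowest covariance over 6 divisions was 0.149, against 0.201 with all controls, which argues against shared controls as the whole cause. A common response to the compound and the mutation, and any condition in which all 3 control samples differed from the other 6, stay open.

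Of 69 plastid-encoded genes, 25 were higher and 4 lower with hyperphyllin and 35 higher and 0 lower in amp1-13. With an estimated correlation the 2 lists had adjusted p = 0.891 and 0.466 with hyperphyllin and 0.293 for both in amp1-13, and with fry the photosynthesis list had 0.301 with hyperphyllin. In amp1-13 the median log2 difference of plastid members exceeded that of mitochondrial members by 0.475 (95% interval over members 0.187 to 0.661), and with hyperphyllin by 0.389 (0.133 to 0.594). These intervals lie above 0, as the test asked for against organelle RNA carried along by the RNA preparation, but do not decide it. Of the mitochondrial members, 6 of 15 lay below the 25th percentile of mean signal. The intervals treat members as independent and leave out the spread between arrays, and the 2 organelles need not be carried along equally. Nuclear photosynthesis genes, whose transcripts are not organelle RNA, were also mostly higher in both effects, and organelle RNA carried along leaves that rise unexplained. For the plastid-encoded genes, organelle RNA carried along and a change in plastid number or plastid transcription stay open. Whole seedlings mix tissues, and a changed share of tissues was not tested.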
